A study of Mus musculus with 24 samples.

How the data were processed

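The libraries were made from the RAW mouse macrophage line, in 2 stable derivatives that carried a doxycycline-inducible construct for Nur77 or for GFP. Per the labels' protocols, the construct was induced with 50 ng/ml doxycycline for 18 h, and the cells then received 500 ng/ml lipopolysaccharide (LPS, a bacterial ligand of Toll-like receptor 4) for 0, 1 or 5 h. RNA was isolated on silica columns with DNase treatment on the column, and libraries were prepared with a KAPA mRNA HyperPrep kit, per the labels' protocols. Each of the 6 groups held 4 libraries, 24 in all, and the titles gave the line, time and replicate number. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Each construct was present in 1 stable line.

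The submitters' processing notes name CASAVA 1.8.2, HISAT2 2.1.0 and the mouse build mm10. The counting tool, its strand setting and the annotation version are not given in the sources used here. The authors deposited 1 table of estimated counts for 42361 RefSeq transcripts in 24 columns, not normalized. All values were multiples of 0.5 (tolerance 1e-09), and 53.7% of the values above 0 were whole. Isoforms of a gene repeated nearly the same counts: over 5011 genes with a mean of at least 50, the median ratio of the second to the highest isoform was 0.992. Summing isoforms would therefore have counted reads more than once, so each gene was represented by its transcript with the highest mean over all libraries. Of the transcripts, 42203 were matched to a gene symbol through the RefSeq gene table of GRCm38.p6, 65 more through GENCODE, and 93 were kept under their own identifiers. The 93 held 0.497% of the counts. The result was 25160 genes, 8193 of them with more than 1 transcript in the table. Coordinates are those of GRCm38, the build also called mm10, and are counted from 1.

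Depth was measured as the sum over these genes, from 8137306 to 29279140 per library; the sums of the whole table, with isoforms repeated, were 15925373.5 to 57880679.5. The estimated counts were rounded to whole numbers before the tests. Genes with low counts were removed with edgeR's filterByExpr by group, which left 12213 genes. Library sizes were scaled by the trimmed mean of M-values (TMM), with factors from 0.896 to 1.14. A model with 6 group means was fitted to all 24 libraries, with 18 residual degrees of freedom and a common biological coefficient of variation of 0.0978, by the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (glmQLFit, glmQLFTest). P-values were adjusted over genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The 9 comparisons were Nur77 against GFP line at each of 3 times, LPS against 0 h at 1 h and 5 h within each line, and the difference of the LPS response between the lines (the interaction) at 1 h and 5 h. Log2 fold changes between lines are positive where the Nur77 line was higher. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM (counts scaled to 1e6 per library) adjusted by TMM, as mean ± SD of 4 libraries.

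Gene lists were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and adjusted over the 27 lists within a comparison. Camera with an estimated correlation, camera on ranks and fry were alternatives. The lists held textbook members of pathways and complexes. Marker lists of fibroblasts, lymphocytes, epithelium and neutrophils were included to look for RNA of other cells.

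The groups, tests, lists and named genes' rule were set before the data were examined. Named in every comparison were Nr4a1, Nr4a2, Nr4a3, Tnf, Il1b, Il6, Il12b, Il10, Nos2, Acod1, Ptgs2, Cxcl10, Ccl2, Ifnb1, Fos and Jun. To these were added the 6 higher and 6 lower genes with the largest change in each comparison of the lines, and the 4 higher and 4 lower genes in each other comparison. These had to be called and reach 10 CPM in the higher group; outside the interactions, CPM of the groups could not overlap. For each list described, up to 4 members with the smallest adjusted p were added. Some genes that this rule names are not reported here. LPS-induced genes at a time were those called with a log2 fold change of at least 1 averaged over both lines, and LPS-repressed genes those with the opposite change; Nr4a1 was left out of these sets. The alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors within edgeR, no filter, a filter of 1 CPM in 4 libraries, a fit of only the groups compared, a replicate block and the omission of each library in turn. The mean over a gene's transcripts, the omission of the transcript NR_046233 and, for 1 library that stood apart, its omission in list tests and in comparisons that do not use it were chosen after seeing the data.

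The fitting steps were tested on simulated counts for 24 libraries, drawn with the mean level and spread of each of 12213 genes and the real library sizes, with 200 genes changed between the lines at 0 h. At an adjusted p under 0.05, 22 of 50 genes changed 1.25-fold, 33 of 50 changed 1.5-fold, 47 of 50 changed 2-fold and 48 of 50 changed 4-fold were recovered, with 7 false calls. Genes with changes under 1.5-fold were thus often missed in the simulation. It changed far fewer genes than the 4863 called between the lines at 0 h, so these shares may not carry over to the real data. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 2.25 to 94.3, so each was counted as a separate library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.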

Results

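Transcript abundance was measured by RNA sequencing in 2 stable derivatives of the RAW mouse macrophage line, one with a doxycycline-inducible construct for Nur77 and one with a construct for GFP. Nur77 is the nuclear receptor encoded by Nr4a1. The study asks how this receptor shapes the inflammatory response of macrophages, with genes controlled by AP-1, the family of Fos and Jun transcription factors, in view. Cells were treated with doxycycline for 18 h and collected after 0, 1 or 5 h of LPS, with 4 libraries in each of the 6 groups. Total counts over 25160 genes were 8137306 to 29279140 per library, and 12213 genes were tested.

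The first principal component of log2 CPM held 48.1% of the variance and followed the time after LPS, and the second held 26.5% and separated the lines. Libraries of a group correlated with each other at 0.988 or higher except in the Nur77 line at 1 h, where the lowest correlation was 0.976. There, replicate 2 lay at 11.6 on the first component and the other 3 libraries between -11.4 and -10.2. Values for that group carry this spread.

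**Figure D1:**
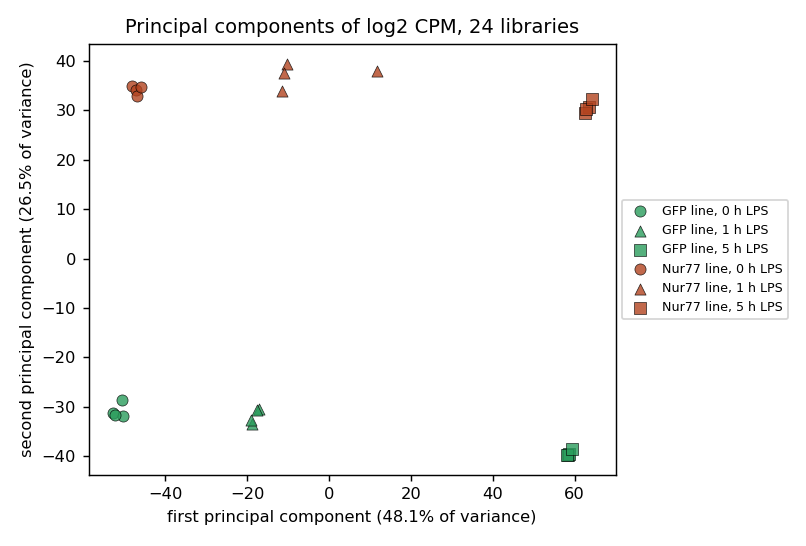
Principal components of log2 CPM for 24 libraries: the horizontal axis is the first component (48.1% of variance), the vertical axis the second (26.5%), colours give the line and symbols the hours of LPS. The lines separate on the vertical axis, and Nur77 line 1 h replicate 2 lies at 11.6 on the horizontal axis against -11.4 to -10.2 for the other 3 libraries.

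Nr4a1 (NM_010444, chromosome 15, 101253902 to 101274795, GRCm38) stood at 3.07 ± 0.376 CPM in the GFP line and 3.29 ± 0.408 CPM in the Nur77 line before LPS (SD, n = 4). The log2 fold change between the lines was 0.09, with a 95% confidence interval from -0.739 to 0.919 and an adjusted p of 0.885, so no difference was detected. The width of this interval rests on the spread over all 24 libraries and not on the 0 h libraries alone. That spread takes in Nur77 line 1 h replicate 2, which stood apart for this gene. The sequence and species of the construct are not given in the sources used here, and reads of a construct that differs from the mouse transcript would not be counted at Nr4a1. This value therefore does not check the labels. After 1 h of LPS Nr4a1 rose by 4.32 on the log2 scale in the GFP line, to 61.8 ± 6.69 CPM, and by 3.32 in the Nur77 line, to 32.9 ± 15.8 CPM. The difference of these rises was not called (interaction -0.996, adjusted p = 0.239), except without Nur77 line 1 h replicate 2 (-0.694, adjusted p = 0.0219). The level at 1 h was lower in the Nur77 line (log2 fold change -0.91, adjusted p = 0.00481). In that group replicate 2 had 9.29 CPM and the other 3 libraries 39.8 to 42.4 CPM. Without replicate 2 the log2 fold change was -0.605 (adjusted p = 1.63e-06), and in a fit of only the 8 libraries compared the call was lost (adjusted p = 0.0822). At 5 h Nr4a1 was at 2.88 ± 0.488 CPM in the GFP line and 4.89 ± 0.318 CPM in the Nur77 line, a log2 difference of 0.73 that did not pass the test over all libraries (adjusted p = 0.113) and passed it with the DESeq2 test (adjusted p = 0.0445) and in the fit of the 8 libraries compared (adjusted p = 0.000362). Against 0 h the Nur77 line was 0.56 higher (adjusted p = 0.20), and the interaction at 5 h was 0.64 (adjusted p = 0.544). Both passed in the fit of only the groups compared (adjusted p = 0.00207 and 0.0344). The related receptor gene Nr4a2 was lower in the Nur77 line at 0, 1 and 5 h, with log2 fold changes of -1.10, -0.91 and -0.88. Nr4a3 was lower at 5 h (-1.19, adjusted p = 8.3e-07).

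The comparison of the lines before LPS asks what Nur77 and GFP cells differ in without stimulation. Among genes that reached 10 CPM in the higher line, the largest differences concerned genes close to silent in the other. Nefh, a neurofilament subunit gene (NM_010904, chromosome 11, 4938754 to 4948064), was at 0.245 ± 0.146 CPM in GFP cells and 98.3 ± 2.72 CPM in Nur77 cells, a log2 fold change of 8.66 (SE 0.25). Alpl, encoding tissue-nonspecific alkaline phosphatase (NM_007431, chromosome 4, 137741731 to 137796384), was 8.65 higher on this scale (SE 0.17), and the chemokine gene Cxcl14, the endothelin-converting enzyme gene Ece1, the netrin and repulsive guidance receptor gene Neo1 and the guanine nucleotide exchange factor gene Rasgrf2 were 7.45, 7.07, 6.35 and 5.51 higher. Lower in Nur77 cells were Scg2, encoding secretogranin II (-7.36), the macrophage metalloelastase gene Mmp12 (-6.82), the carboxypeptidase gene Cpe (-5.63), the leukocyte receptor gene Cd84 (-5.63), Layn, a hyaluronan receptor gene (-5.47) and Dio2, the type 2 deiodinase gene (-4.91). In all, 4863 genes were called, 2463 higher and 2400 lower in the Nur77 line, of which 308 and 605 changed by at least 1 on the log2 scale.

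Among the lists, 26 genes of the NF-kB pathway, which drives inflammatory transcription, and its feedback inhibitors moved together at 0 h: 20 were higher, 2 lower and 4 not called, with 20 and 2 also when adjusted over the list alone (camera adjusted p = 2.75e-07, and adjusted p = 0.000952 with an estimated correlation). Traf1, an adaptor of tumour necrosis factor receptors, was 1.91 higher, Tnfaip3, encoding the deubiquitinase A20 that limits NF-kB signalling, 1.56 higher (SE 0.08), Tnip3 1.24 higher and the apoptosis inhibitor gene Birc3 0.82 higher. Of 20 macrophage identity genes 13 were lower and 1 higher, as when adjusted over the list alone (camera adjusted p = 9.09e-06, and adjusted p = 0.0430 with an estimated correlation). The lectin gene Lgals3 (-1.87), the cathepsin S gene Ctss (-1.35) and the perforin-like gene Mpeg1 (-1.26) were among them. Cell cycle genes were higher, 32 of 37 with 1 lower, and 33 and 1 adjusted over the list alone (camera adjusted p = 2.74e-09). Glycolysis genes were lower, 16 of 20 with none higher in either adjustment, among them the hexokinase gene Hk3 (-1.22) and the lactate dehydrogenase gene Ldha (-0.63), with a camera adjusted p of 1.65e-07. With an estimated correlation neither was called, at adjusted p = 0.183 for the cell cycle list and adjusted p = 0.143 for glycolysis.

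The remaining 5 calls of camera at 0 h were also lost with an estimated correlation. Chemokines were higher in 8 of 17 and lower in 2, in both adjustments (camera adjusted p = 0.0208, adjusted p = 0.137 with an estimated correlation, adjusted p = 0.0540 without Nur77 line 1 h replicate 2), with Ccl22 at 3.51 and Cxcl10 at 3.39. Levels of these were low, with 15 and 27 counts summed over the GFP libraries and 144 and 235 over the Nur77 libraries. Genes of LXR, the sterol-sensing nuclear receptor, and of lipid handling were lower in 11 of 22 and higher in 3, in both adjustments (adjusted p = 0.00570, and adjusted p = 0.143 with an estimated correlation). The fatty acid binding protein gene Fabp5 was lower there (-2.20), as was the cholesterol transport gene Npc2 (-1.05), which lies on chromosome 12, and the scavenger receptor gene Cd36 was higher (1.49). Osteoclast markers were lower in 5 of 10 and higher in 2, in both adjustments (adjusted p = 0.0491, and adjusted p = 0.143 with an estimated correlation), with the proton pump subunit gene Atp6v0d2 at -4.75 and the integrin gene Itgb3 at -4.03. Citric acid cycle genes were lower in 11 of 25 and higher in 4 in both adjustments (adjusted p = 0.0276, and adjusted p = 0.210 with an estimated correlation). Genes of the integrated stress and unfolded protein responses were higher in 12 of 27 and lower in 5, and 14 and 5 adjusted over the list alone (adjusted p = 0.0220, and adjusted p = 0.491 with an estimated correlation).

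AP-1 subunits and targets, the subject of the study's question, were mixed before LPS. Of 18 AP-1 and related subunit genes 3 were higher and 8 lower in both adjustments, a list difference that did not pass (camera adjusted p = 0.0859). Fos (NM_010234, chromosome 12, 85473890 to 85477274) was at 18.2 ± 1.00 CPM in GFP cells and 4.57 ± 0.282 CPM in Nur77 cells, a log2 fold change of -1.99 (SE 0.12, adjusted p = 9.2e-13), and Atf3 was lower (-1.44) while Jun was higher (0.46, adjusted p = 0.01). Of 28 textbook AP-1 target genes 4 were higher and 11 lower in both adjustments (camera adjusted p = 0.0809); without Nur77 line 1 h replicate 2 this list was called as lower (adjusted p = 0.0473, and adjusted p = 0.118 with an estimated correlation). Among them Mmp12 and the heme oxygenase gene Hmox1 (-1.35) were lower and the integrin gene Itgav was higher (1.44). Of the inflammatory panel, Tnf was higher (1.23, adjusted p = 1.4e-06), at 51.2 against 21.9 CPM. The nitric oxide synthase gene Nos2 was lower (-3.64, adjusted p = 0.00012), near the floor, with 5 counts summed over the Nur77 libraries and 82 over the GFP libraries. Acod1 was called higher (0.864, adjusted p = 0.0217) and Ccl2 lower (-1.38, adjusted p = 0.0362). These 2 calls were lost in 4 of 8 and 7 of 8 omissions of 1 library. Il1b and Ptgs2 were not called at 0 h (adjusted p = 0.54 and 0.13), though Ptgs2 was called by DESeq2 (adjusted p = 0.0159) and in the fit of the 8 libraries (adjusted p = 0.00395).

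At 1 h of LPS the lines again differed most, among genes that reached 10 CPM, in Nefh (9.33), Cxcl14 (8.28), Alpl (8.28) and Ece1 (7.57) on the higher side and in Mmp12 (-6.48), Cd84 (-5.70), Scg2 (-5.06) and Atp6v0d2 (-4.98) on the lower side. In total 6259 genes were called, 3235 higher and 3024 lower, with 360 and 659 at a log2 change of at least 1. Chemokine genes were higher in the Nur77 line, 10 of 17 with 1 lower in both adjustments (camera adjusted p = 0.00522, and adjusted p = 0.116 with an estimated correlation), among them Cxcl11 (3.45) and Cxcl10 (2.20), ligands of the receptor CXCR3 and targets of interferon. Tnf stood at 2518 ± 153 CPM in the GFP line and 4265 ± 1445 CPM in the Nur77 line (log2 fold change 0.76, adjusted p = 0.00014), and the prostaglandin synthase gene Ptgs2 was higher as well (1.12, adjusted p = 0.0014). Without replicate 2 of the Nur77 line these log2 fold changes were 0.503 for Tnf and 0.546 for Ptgs2, and both genes were still called. Il1b was lower (-0.73, adjusted p = 0.0012). Ccl2 and Il6 were not called (adjusted p = 0.30 and 0.062), but without that library their log2 fold changes were -1.74 (adjusted p = 1.04e-15) and -2.99 (adjusted p = 1.68e-06), and Il6 was also called without GFP line 1 h replicate 4 (-1.53, adjusted p = 0.0300). Il6 was near the floor, with 6, 7 and 0 counts in Nur77 line replicates 1, 3 and 4 and 15 to 56 in the GFP libraries. The size of its difference is therefore uncertain. Stress response genes were higher in 19 of 27 and lower in 1 in both adjustments (camera adjusted p = 1.45e-05, and adjusted p = 0.312 with an estimated correlation). These included Herpud1 (0.98), which takes part in degradation from the endoplasmic reticulum, and the growth factor gene Manf (0.95).

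NF-kB genes at 1 h were higher in 16 of 26 and lower in 3 in both adjustments (camera adjusted p = 0.0171, and adjusted p = 0.116 with an estimated correlation). The inhibitor gene Nfkbia (-0.55) and Tnfaip2 (-1.27), both on chromosome 12, were lower and Socs3, a brake on cytokine signalling, was higher (0.65). AP-1 subunits were higher in 4 and lower in 6 of 18 in both adjustments (camera adjusted p = 0.650), with Fosl1 at 1.68, Atf3 at -1.11 and Fos at -0.73. AP-1 targets were higher in 7 and lower in 7 of 28 in both adjustments (camera adjusted p = 0.318), and without replicate 2 of the Nur77 line the list was called as lower (adjusted p = 0.0111, and adjusted p = 0.0587 with an estimated correlation). The leukaemia inhibitory factor gene Lif (-1.96), a member of that list and of the cytokine list, was lower. Glycolysis (13 of 20 lower, camera adjusted p = 5.98e-05, adjusted p = 0.300 with an estimated correlation), macrophage identity (12 of 20 lower and 2 higher, 0.000346, adjusted p = 0.116 with an estimated correlation) and cell cycle lists (22 of 37 higher and 1 lower, 1.45e-05, adjusted p = 0.362 with an estimated correlation) moved as at 0 h. LXR and citric acid cycle genes were also lower, 11 of 22 and 12 of 25 with 2 higher in each (adjusted p = 0.00533 and 0.0171, with adjusted p = 0.180 and adjusted p = 0.279 with an estimated correlation). Adjusted over the list alone, the cell cycle list had 23 higher and the LXR list 12 lower, and the other counts stayed.

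At 5 h of LPS 5663 genes differed between the lines, 2680 higher and 2983 lower, with 285 and 815 at a log2 change of at least 1. Nefh (8.50), Alpl (8.43) and Cxcl14 (7.59) led the higher genes that reached 10 CPM again, and the scaffold gene Akap12 joined them (5.27). Mmp12 (-5.75), Cpe (-5.34), Cd84 (-5.32) and Acp5, encoding the tartrate-resistant acid phosphatase of osteoclasts (-4.92), led the lower genes. Of the inflammatory panel, Nos2 was at 396 ± 30.8 CPM in the GFP line and 98.9 ± 6.92 CPM in the Nur77 line, a log2 fold change of -2.00 (SE 0.14, adjusted p = 4.7e-11). Il1b (-0.95), Ccl2 (-1.79) and Il12b (-1.86) were lower too, and Cxcl10 was higher (1.60, adjusted p = 3e-06). Tnf, Il6, Acod1 and Ptgs2 had log2 fold changes of 0.29, -0.56, -0.28 and -0.44 and were not called over all libraries (adjusted p from 0.10 to 0.17). In the fit of only the 8 libraries compared each passed, with the largest adjusted p at 7.14e-05.

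Textbook AP-1 target genes were lower in the Nur77 line at 5 h in 16 of 28 and higher in 3, and 16 and 4 adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.444 with an estimated correlation). Mmp12, Lif (-1.33) and Hmox1 (-1.15) were among the lower ones. The subunits themselves were higher in 5 and lower in 5 of 18 in both adjustments (camera adjusted p = 0.733), with Atf3 at -1.74, Jund at -1.22, Batf, which lies on chromosome 12, at -2.19, Jun at 0.82 and Fos at 0.04 (adjusted p = 0.82 for Fos). NF-kB genes were higher in 4 and lower in 11 of 26 in both adjustments (camera adjusted p = 0.286), and inflammatory cytokines higher in 2 and lower in 11 of 23 in both adjustments (camera adjusted p = 0.0662). Macrophage effector genes were lower in 12 of 18 and higher in 2 in both adjustments (camera adjusted p = 0.00662, and adjusted p = 0.119 with an estimated correlation), with the acute phase gene Saa3 at -1.17 and the arginase gene Arg2 on chromosome 12 at -2.30. Adhesion genes were lower in 13 of 24 and higher in 5, and 14 and 6 adjusted over the list alone (adjusted p = 0.0475, and adjusted p = 0.219 with an estimated correlation), as shown by the intermediate filament gene Vim (-1.21) and the integrin gene Itgax (-2.83). Osteoclast markers were lower in 7 of 10 and higher in 2 (adjusted p = 0.0146, and adjusted p = 0.119 with an estimated correlation). The macrophage identity list (14 of 20 lower, 2 higher, camera adjusted p = 0.000854), glycolysis (14 of 20 lower, 0.00119), LXR targets (13 of 22 lower, 2 higher, 0.0202), the citric acid cycle (13 of 25 lower, 1 higher, 0.0219), the cell cycle (26 of 37 higher, 3 lower, 5.71e-05) and stress responses (15 of 27 higher, 1 lower, 0.000101) kept the direction seen at 0 h. Adjusted over the list alone, 3 LXR genes, 27 cell cycle genes and 16 stress response genes were higher, and the other counts stayed. None of these 6 was called with an estimated correlation, where the adjusted p ranged from 0.119 for macrophage identity to 0.309 for the cell cycle.

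The differences between the lines recurred over time. In the same direction at 0, 1 and 5 h, from separate libraries, 1303 genes were higher and 1617 lower, 2920 together; 288 would be shared by independent lists of these sizes. Across the 12213 genes, which are not independent replicates, the log2 fold changes between the lines correlated at 0.85 for 0 h with 1 h, 0.81 for 0 h with 5 h and 0.84 for 1 h with 5 h (Pearson).

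Genes on chromosome 12 were lower as a group in the Nur77 line, a pattern looked for after the values were seen. The median log2 fold change of its 435 tested genes was -0.41 at 0 h, -0.44 at 1 h and -0.46 at 5 h. At 0 h the medians of the other 19 chromosomes lay between 0.003 and 0.08. On chromosome 12, 285 genes were called lower and 14 higher at 0 h. Fos, Nfkbia, Tnfaip2, Batf, Arg2, Npc2 and Dio2, named above, lie on this chromosome. Within each line the median LPS response of chromosome 12 genes was between -0.03 and 0.02 at both times.

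**Figure D2:**
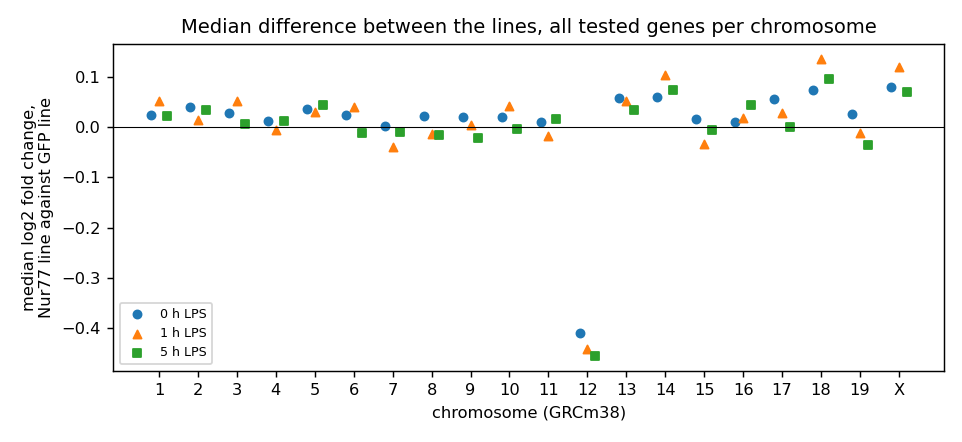
Median log2 fold change of the Nur77 line against the GFP line (vertical axis) over all tested genes of each chromosome (horizontal axis, GRCm38), with circles for 0 h, triangles for 1 h and squares for 5 h of LPS. Chromosome 12 lies at -0.41, -0.44 and -0.46, and at 0 h the other chromosomes lie between 0.003 and 0.08.

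The response to LPS within the GFP line gives the background for the Nur77 line. After 1 h the chemokine gene Cxcl2 rose by 8.43 on the log2 scale, Cxcl10 by 8.05, the NF-kB cofactor gene Nfkbiz by 7.99 and Acod1, encoding the itaconate-producing enzyme, by 7.34. Tnf went from 21.9 ± 3.91 to 2518 ± 153 CPM, a rise of 6.85 (SE 0.19, adjusted p = 1.2e-18). Txnip, which encodes a thioredoxin inhibitor, fell by 1.79, and Hhex, a homeobox gene, fell by 1.36. Of 2121 called genes 1189 rose and 932 fell, with 312 and 133 at a log2 change of at least 1. Immediate early genes rose in 28 of 31 with 1 lower, NF-kB genes in 24 of 26, chemokines in 13 of 17 and AP-1 subunits in 14 of 18 with 1 lower, the same counts adjusted over each list alone. Cytokines rose in 17 of 23 and AP-1 targets in 20 of 28, and 18 and 23 with 1 target lower adjusted over the list alone. Each of these 6 lists was called with the preset and with an estimated correlation, the largest adjusted p being 0.00339 for AP-1 targets with an estimated correlation. Tnfaip3 (6.82), Egr2 (6.12), Maff (4.58) and Nfkbia (4.59) were members. Fos rose by 0.62 and Jun by 2.85.

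MAP kinase feedback inhibitors (8 of 15 higher, 1 lower), macrophage effector genes (10 of 18 higher), apoptosis regulators (8 of 23 higher, 4 lower) and cholesterol biosynthesis genes (5 of 22 higher) were called at 1 h in the GFP line with both correlations, the largest adjusted p being 0.0202 for cholesterol biosynthesis with an estimated correlation. Dusp1, a MAP kinase phosphatase gene, rose by 4.61. Adjusted over the list alone, these counts were 9 and 1, 10 and 0, 8 and 4, and 7 and 0. Toll-like receptor signalling (9 of 27 higher, 4 lower), antigen presentation (3 of 13 higher) and stress responses (8 of 27 higher, 1 lower) were called with the preset correlation (adjusted p = 0.0189, 0.00530 and 0.000564). These calls were lost with an estimated correlation (adjusted p = 0.171, adjusted p = 0.0645 and adjusted p = 0.321). For these, 5 Toll-like receptor genes were lower and 9 stress response genes higher when adjusted over the list alone.

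After 5 h in the GFP line 7642 genes were called, 3741 higher and 3901 lower, 1027 and 948 of them by at least 1 on the log2 scale. The granulocyte colony stimulating factor gene Csf3 rose by 12.39 (SE 1.04), Il1b by 11.90 (SE 0.30), from 0.266 ± 0.196 to 932 ± 19.2 CPM, and Acod1 by 11.10. Ccl17 had no counts at 0 h and stood at 12.7 ± 0.578 CPM at 5 h. Nos2 rose by 8.44, Il6 by 8.49 and Ptgs2 by 10.08. Il6, Csf3 and Il1b started from 5, 14 and 17 counts summed over the 0 h libraries, so the size of their rises is uncertain. The chemokine receptor gene Cxcr4 fell by 4.22, and the sialyltransferase gene St6gal1 fell by 4.04. Fos, which had risen at 1 h, fell by 2.12 against its 0 h level. Interferon-stimulated genes, not called as a list at 1 h (10 of 50 higher, 7 lower, camera adjusted p = 0.122), rose in 48 of 50 at 5 h, and 49 adjusted over the list alone (camera adjusted p = 1.22e-26, adjusted p = 2.18e-07 with an estimated correlation), with Oasl1 at 6.86 and Rtp4 at 6.45. All 23 cytokine genes, 16 of 17 chemokines, 25 of 26 NF-kB genes with 1 lower, 16 of 18 effector genes with 2 lower and 12 of 13 antigen presentation genes with 1 lower rose, in both adjustments. These were called with both correlations (largest adjusted p = 0.00872). AP-1 targets (25 of 28 higher, 1 lower), AP-1 subunits (13 of 18 higher, 4 lower), immediate early genes (23 of 31 higher, 6 lower), MAP kinase inhibitors (11 of 15 higher, 1 lower) and Toll-like receptor genes (18 of 27 higher, 3 lower) were too, with a largest adjusted p of 0.0288 with an estimated correlation. There were 26 AP-1 targets higher and 7 immediate early genes lower when adjusted over the list alone.

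Cell cycle genes fell in 36 of 37 at 5 h in the GFP line in both adjustments (camera adjusted p = 1.77e-12, and adjusted p = 0.0769 with an estimated correlation), among them Cdc6, a replication licensing gene, which fell by 2.16, and the cyclin gene Ccne1, which fell by 1.79. Histone genes, chosen by symbol and with the linker histone gene H1f0 among them, fell in 9 of 16 (adjusted p = 0.0106, and adjusted p = 0.139 with an estimated correlation). The list is therefore not limited to replication-dependent genes. Near-identical histone copies can share reads, so single histone genes are uncertain. Adhesion genes (13 of 24 higher, 4 lower) and stress responses (13 of 27 higher, 4 lower) were called only with the preset correlation (adjusted p = 0.0333 and 0.0366, against adjusted p = 0.0721 and adjusted p = 0.561 with an estimated correlation).

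The Nur77 line was asked the same question. At 1 h 5406 genes were called, 2749 higher and 2657 lower, 417 and 297 of them by at least 1 on the log2 scale; the fit of only the 8 libraries compared called 3490. Cxcl2 rose by 8.37, Acod1 by 7.10, Il1b by 7.29 and Tnf by 6.38, from 51.2 ± 4.80 to 4265 ± 1445 CPM. Il1b started from 8 counts summed over the 0 h libraries, so the size of its rise is uncertain. Sele, the endothelial selectin gene, went from 0.0297 ± 0.0594 to 37.1 ± 29.98 CPM. Rgs2, a regulator of G protein signalling, fell by 1.97 and Txnip fell by 2.05. Fos rose by 1.88. The lists called at 1 h with both correlations were the AP-1 subunits (14 of 18 higher, 1 lower), AP-1 targets (23 of 28, 1 lower), cytokines (18 of 23), chemokines (13 of 17), NF-kB genes (25 of 26), immediate early genes (28 of 31, 2 lower), MAP kinase inhibitors (9 of 15), effector genes (12 of 18) and apoptosis regulators (10 of 23, 4 lower), the largest adjusted p being 0.0291. Antigen presentation genes rose in 6 of 13 with 1 lower (adjusted p = 0.0103, and adjusted p = 0.0939 with an estimated correlation), and stress response genes in 18 of 27 (adjusted p = 2.36e-06, and adjusted p = 0.218 with an estimated correlation), with the phosphatase regulator gene Ppp1r15a at 4.65. Adjusted over the list alone, 1 chemokine was lower, 11 apoptosis regulators were higher, and 19 stress response genes were higher and 1 lower.

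At 5 h in the Nur77 line 8134 genes were called, 3969 higher and 4165 lower, with 1014 and 1237 at a log2 change of at least 1. Il1b rose by 11.73 to 483 ± 18.9 CPM, Csf2 by 11.66, Il1a by 10.19 and Nos2 by 10.07 to 98.9 ± 6.92 CPM. Il1b, Csf2 and Nos2 started from 8, 14 and 5 counts summed over the 0 h libraries, so the size of their rises is uncertain. Rab7b, a gene of lysosomal trafficking, fell by 4.30, the Wnt antagonist gene Dkk2 fell by 4.24 and the uracil glycosylase gene Ung fell by 3.86. Fos was not called against 0 h (-0.09, adjusted p = 0.60). Interferon-stimulated genes rose in 48 of 50 with 1 lower in both adjustments (camera adjusted p = 2.7e-24, adjusted p = 4.46e-07 with an estimated correlation). Cytokines (22 of 23), chemokines (16 of 17, 1 lower), NF-kB genes (25 of 26, 1 lower), effector genes (16 of 18, 2 lower), immediate early genes (23 of 31, 2 lower), AP-1 subunits (13 of 18, 1 lower), antigen presentation (11 of 13, 1 lower) and MAP kinase inhibitors (9 of 15, 1 lower) rose with both correlations (largest adjusted p = 0.0242). The calls of AP-1 targets (23 of 28 higher, 2 lower, adjusted p = 2.1e-10) and Toll-like receptor genes (15 of 27 higher, 7 lower, adjusted p = 0.00939) were lost with an estimated correlation (adjusted p = 0.0501 and adjusted p = 0.129). So were those of the cell cycle (35 of 37 lower), histones (9 of 16 lower, 1 higher), glycolysis (10 of 20 higher, 3 lower), stress responses (15 of 27 higher, 3 lower) and ribosomal protein genes (29 of 79 higher), at adjusted p = 0.103, adjusted p = 0.239, adjusted p = 0.504, adjusted p = 0.413 and adjusted p = 0.606. Ribosomal protein genes have many processed copies, and their changes were small, such as 0.27 for Rpl24. Adjusted over the list alone, 2 AP-1 subunits and 3 immediate early genes were lower and 21 ribosomal protein genes higher.

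**Figure D3:**
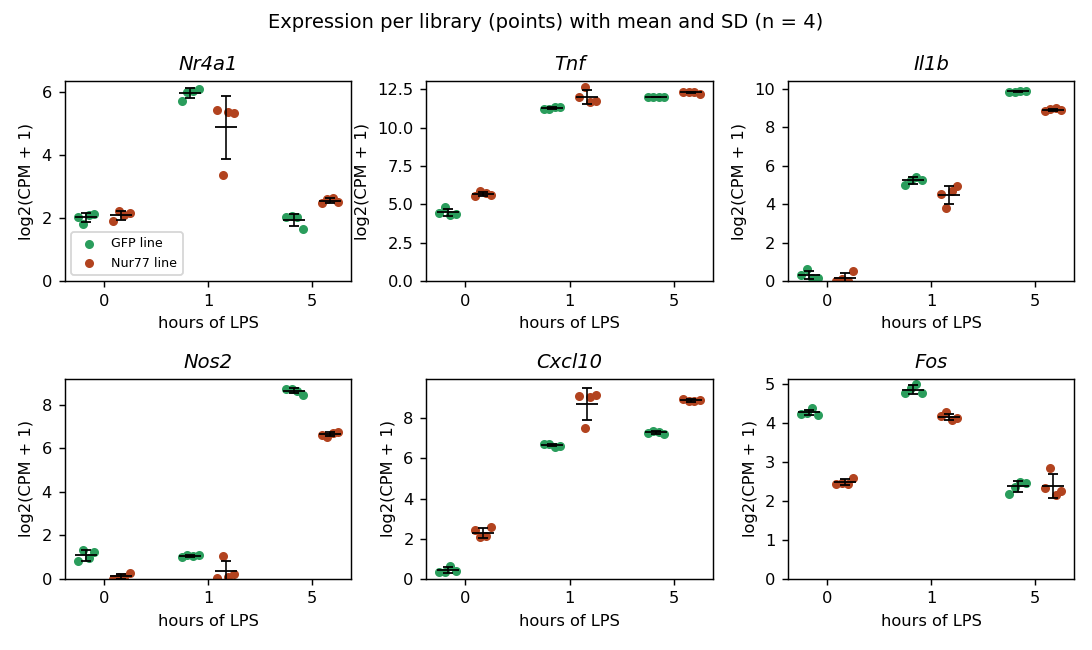
Expression of 6 genes as log2(CPM + 1) (vertical axis) against hours of LPS (horizontal axis), with 1 point per library, green for the GFP line and brown for the Nur77 line, and bars for mean and SD of 4 libraries. At 5 h Nos2 stands at 396 CPM in the GFP line and 98.9 CPM in the Nur77 line, and in the Nur77 line at 1 h replicate 2 stands apart for Nr4a1 (9.29 CPM against 39.8 to 42.4 CPM).

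Whether the lines responded differently to LPS was tested by the interaction. Across genes the LPS responses of the lines correlated at 0.81 at 1 h and 0.92 at 5 h (Pearson, 12213 genes). At 1 h Tnfaip3 rose 1.45 less in the Nur77 line on the log2 scale (interaction -1.45, SE 0.10, adjusted p = 1.8e-09), from a higher start of 22.8 ± 1.63 against 7.80 ± 0.805 CPM, and reached 942 ± 85.9 against 876 ± 12.6 CPM. Nfkbia (interaction -1.28, adjusted p = 2.2e-09), Traf1 (-1.34), Ccl22 (-1.87) and the interferon regulatory factor gene Irf1 (-1.82, adjusted p = 0.0016) also rose less. Ccl22 started higher in the Nur77 line, with 144 against 15 summed counts, and had 909 against 235 at 1 h. Nfkbia lies on chromosome 12. Fos (interaction 1.27, SE 0.16, adjusted p = 4e-05), the zinc finger factor gene Egr1 (1.54), the stress gene Ddit4 (1.39) and Ppp1r15a (1.34) rose more, all 4 from lower starts. Egr1 was at 106 ± 11.7 CPM at 0 h in the GFP line and 17.4 ± 1.23 CPM in the Nur77 line. NF-kB genes as a list rose less on the log2 scale, 6 of 26 lower in the interaction and none higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000278, and adjusted p = 0.0148 with an estimated correlation). Most of the list was higher in the Nur77 line at 0 h, and still at 1 h, so the smaller rise is not separate from the higher start. Without Nur77 line 1 h replicate 2 the list remained below 0.05 with the preset correlation (adjusted p = 0.00324) and did not with an estimated one (adjusted p = 0.0629). AP-1 subunits (1 of 18 higher; 6 higher and 2 lower adjusted over the list alone) and stress responses (2 of 27 higher, 7 adjusted over the list alone) were called as higher (adjusted p = 0.0267 and 6.3e-05), and not with an estimated correlation (adjusted p = 0.0650 and adjusted p = 0.922). AP-1 targets were not called (1 higher and 2 lower of 28, camera adjusted p = 0.779).

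In total 144 genes were called in the 1 h interaction, 77 higher and 67 lower, 11 and 18 of them by at least 1, and this count was unstable: 500 with DESeq2, 95 without a filter and 47 in the fit of only the 16 libraries compared. Leaving out 1 library gave 1589 (Nur77 line 1 h replicate 1), 608 (replicate 4), 221 (replicate 2) and 87 (replicate 3), 74 (GFP line 0 h replicate 4), 81, 93 and 83 (GFP line 1 h replicates 2, 3 and 4) and 78, 82 and 87 (Nur77 line 0 h replicates 2, 3 and 4).

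At 5 h NF-kB genes again rose less on the log2 scale in the Nur77 line. Most of them were higher in that line at 0 h, so the smaller rise is not separate from that start. Their levels at 5 h were not called as a list between the lines. In the interaction, of 26, 14 were lower and none higher, and 18 and 1 adjusted over the list alone (camera adjusted p = 2.06e-15, and adjusted p = 4.53e-06 with an estimated correlation). Tnfaip3 (-1.43), Nfkbia (-1.31), Traf1 (-2.10) and Birc3 (-1.10) were members. Traf1 went from 0.875 ± 0.286 to 299 ± 7.19 CPM in the GFP line and from 3.50 ± 0.278 to 262 ± 14.1 CPM in the Nur77 line. Ccl22 (-2.99), Irf1 (-2.17), the scaffold gene Ppfia3 (-2.28) and Tnf (-0.94, adjusted p = 0.0064) rose less on the log2 scale as well. Tnf and Ccl22 started higher in the Nur77 line and were not lower there at 5 h, so their smaller rise is not separate from that start. At 0 and 5 h Tnf was at 21.9 and 4139 CPM in the GFP line and 51.2 and 5065.5 CPM in the Nur77 line. Ccl22 had 15 and 19518 summed counts in the GFP line and 144 and 23849 in the Nur77 line. Marcks, encoding a substrate of protein kinase C, had a negative interaction of -5.63 (SE 0.41), going from 0.182 ± 0.0779 to 45.2 ± 1.38 CPM in GFP cells and from 4.07 ± 0.451 to 19.96 ± 2.49 CPM in Nur77 cells. Akap12 (3.53), Fos (2.04, adjusted p = 3e-08), the interferon-induced protease gene Usp18 (2.03) and Egr1 (1.65) had positive interactions. For Fos this was a fall of 2.12 in the GFP line, to 4.18 ± 0.495 CPM, beside 4.57 ± 0.282 and 4.31 ± 1.22 CPM at 0 and 5 h in the Nur77 line.

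AP-1 subunits were called as higher in the 5 h interaction (4 of 18 higher and 2 lower, 4 and 3 adjusted over the list alone, camera adjusted p = 0.0205), and not with an estimated correlation (adjusted p = 0.0596). AP-1 targets were not called (4 of 28 lower, none higher in both adjustments, camera adjusted p = 0.646). Cholesterol biosynthesis genes were called as higher in this interaction, 5 of 22 with none lower in both adjustments (adjusted p = 0.00747, and adjusted p = 0.0331 with an estimated correlation). Among them were Hmgcs1 (0.85), Insig1 (0.52) and Dhcr7 (0.47). A positive value was not always a larger rise, since Dhcr7 fell in both lines. Its summed counts at 0 and 5 h were 3482 and 1263 in the GFP line and 2145 and 1125 in the Nur77 line. Without Nur77 line 1 h replicate 2 the list's adjusted p with an estimated correlation was 0.0746. Immediate early genes (8 of 31 higher, 3 lower), glycolysis (3 of 20 higher), stress responses (5 of 27 higher) and ribosomal protein genes (none of 79 called) were called as higher with the preset correlation (largest adjusted p = 0.0250). With an estimated one they were not, at adjusted p = 0.232, adjusted p = 0.568, adjusted p = 0.568 and adjusted p = 0.702. When adjusted over the list alone, 9 immediate early genes were higher and 5 lower, and 4 glycolysis genes higher and 2 lower. In all 970 genes were called at 5 h, 343 higher and 627 lower, 53 and 126 of them by at least 1. The fit of only the 16 libraries compared called 2084, and the fit over all libraries without Nur77 line 1 h replicate 2, which enters the shared estimate of spread, called 1672.

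**Figure D4:**
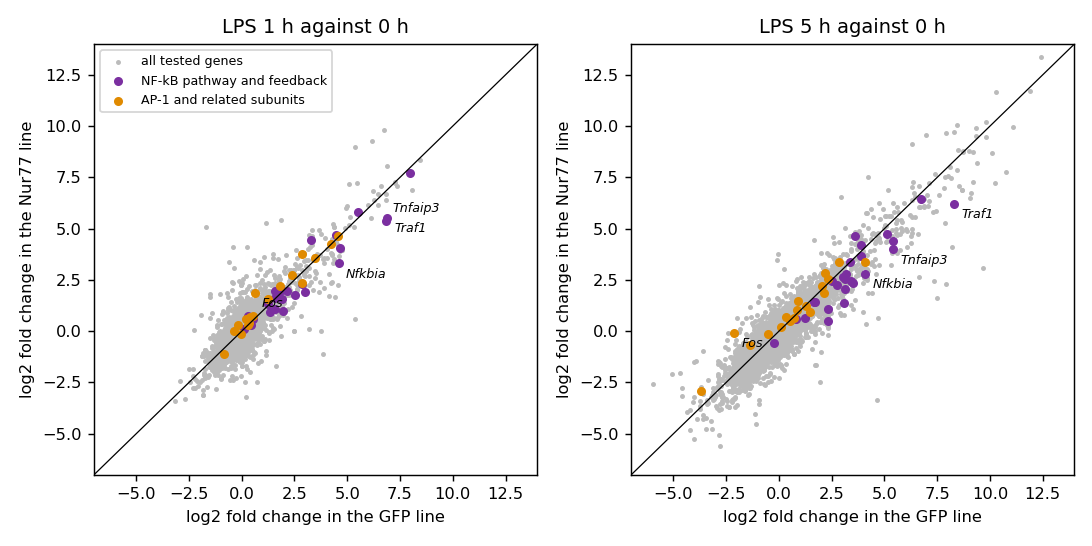
Log2 fold change after LPS in the GFP line (horizontal axis) and the Nur77 line (vertical axis) at 1 h (left) and 5 h (right); grey points are all 12213 tested genes, purple points NF-kB pathway and feedback genes, orange points AP-1 and related subunit genes, and the line marks equal responses. Tnfaip3 lies below the line by 1.45 at 1 h and Traf1 by 2.10 at 5 h, and Fos lies above it.

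The last comparison asks whether genes that LPS induced were lower in the Nur77 line. At 1 h 355 genes were induced over both lines. Of these, 85 (23.9%) were lower in the Nur77 line at that time and 121 (34.1%) higher, beside 24.8% and 26.3% of the other genes, and the set did not shift against other genes (camera p = 0.369, and p = 0.317 with an estimated correlation). At 5 h 1015 genes were induced, of which 356 (35.1%) were lower and 239 (23.6%) higher, beside 23.5% and 21.8% of the other genes (camera p = 0.0782, and p = 0.445 with an estimated correlation). Of the 356, 185 were also lower at 0 h, and of the 239, 123 were also higher at 0 h. Of 197 repressed genes at 1 h, 50 (25.4%) were lower and 14 (7.11%) higher, beside 24.8% and 26.8% of the other genes (camera p = 0.00198, and p = 0.0167 with an estimated correlation). Of 1069 at 5 h, 380 (35.5%) were lower and 142 (13.3%) higher, beside 23.4% and 22.8% of the other genes (camera p = 0.00189, and p = 0.325 with an estimated correlation).

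Of markers of other cells, Pdgfrb was the only tested fibroblast marker, at a mean of 0.855 CPM, and Lck the only tested lymphocyte marker, at 10.1 CPM. No epithelial marker passed the filter, the highest being Cldn7 at 0.07 CPM. The 2 tested neutrophil markers, S100a8 and Csf3r, were not called as a list in any of the 9 comparisons (lowest camera adjusted p = 0.178). Il10 and Ifnb1 stayed below the filter, with at most 6 and 20 counts summed over the 4 libraries of a group. This depth does not allow a comparison of either.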

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

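The tests weighed below for the library that stands apart, for Nr4a1, for chromosome 12 and for the stable lines were chosen after the results were seen; those for chromosome segments and for other splits of the samples were written before.

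In 120 tests of groups of 4 libraries, 15 had 1 library far from the other 3, its gap to the nearest taking 0.84 or more of the group's range, and about 1 in 20 groups would do so by chance. In the Nur77 line at 1 h, replicate 2 was the distant library for the first principal component (0.946 of the range), Nr4a1 (0.922), Il6 (0.889), Nos2 (0.867), Ptgs2 (0.84), Cxcl10 (0.887) and Ccl2 (0.98). In the Nur77 line at 0 h, replicate 4 was the distant library for Il1b (0.849), Il6 (1), Il12b (1) and Fos (0.893); the values for Il6 and Il12b rest on 2 and 1 counts beside 0 in the other libraries and show nothing. In the GFP line at 5 h, replicate 4 was for the second principal component (0.866) and Nr4a1 (0.934). In the GFP line at 0 h, replicate 2 was for Acod1 (0.961) and replicate 1 for Ccl2 (0.94).

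Replicate 2 of the Nur77 line at 1 h differed from the other 3 libraries of its group in 255 genes, 156 higher and 99 lower, among them Lcn2 (71.1 against 3.51 CPM) and Cx3cr1 (18.4 against 110 CPM). A mixture with RNA of the 5 h group is argued against as the whole cause, since 35.29% of these genes lay outside the range between the other 1 h libraries and the 5 h group by more than 1.5-fold, but as a part of it stays open, since for the other 3 libraries 55.56 to 83.33% of 5 to 9 deviating genes did; Upp1 was at 33.2 CPM, with 0.689 and 17.9 CPM there. A label that belongs to another group is argued against, since the library was nearer to its own group mean than to any other by 0.189 (root mean square log2 distance). Counts taken up by NR_046233 are argued against, since it held 1.715% of this library and 1.69% of replicate 3, which did not stand apart. That 61.18% of the deviating genes were higher adds little, since so small a share could not lower a gene 2-fold. A longer or stronger exposure to LPS, or a culture in another state, stays open and was not tested, since the labels record neither for a single library.

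Nr4a1, the mouse gene that encodes Nur77, was not called higher in the Nur77 line at 0 h. An induced construct that raised the counts at the mouse gene by 1 or more on the log2 scale is argued against at 0 h. The upper end of the 95% interval was 0.919, with the spread taken over all 24 libraries and not over the 0 h libraries alone. A smaller rise stays open, and at 5 h each Nur77 library (4.52 to 5.20 CPM) lay above each GFP library (2.15 to 3.16 CPM). A construct that was not induced in these libraries cannot be told apart from a construct with a sequence that the table does not count, with the log2 fold change at 0.09, since the sequence is not given in the sources used here. A biological explanation was not tested.

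The difference between the lines was there before LPS and recurred at all 3 times in 2920 genes. Gain or loss of chromosome segments as the whole cause is argued against, since the median of neighbouring genes predicted 0.62% of the variance of the log2 fold change at 0 h. For the genes on chromosome 12 a lower copy number in the Nur77 line than in the GFP line fits. At 0 h 100% of its windows of 20 genes had a median below -0.2, against 10 of 578 windows elsewhere. Dio2 and Fos, which lie there, differed at 0 h by more than the chromosome's median of -0.41, so copy number does not settle single genes. An effect of Nur77 and a difference between the stable lines that does not come from the construct cannot be told apart for the 2920 genes, since each construct was in 1 line. This holds for the 2687 of them not on chromosome 12 and, beside copy number, for those on it.

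The LPS response differed between the lines by a test of the interaction, in 144 genes at 1 h and 970 at 5 h. At 1 h the log2 differences were Fos 1.27, Scg2 2.30, Egr1 1.54, Ddit4 1.39, Ppp1r15a 1.34, Ccl22 -1.87, Irf1 -1.82, Tnfaip3 -1.45 and Traf1 -1.34; the call of Scg2 was lost in 12 of 16 omissions of 1 library, with the replicate block (adjusted p = 0.0847) and without a filter (0.0517). At 5 h they were Tnf -0.94, Acod1 -1.15, Fos 2.04, Akap12 3.53, Kcnq1ot1 3.13, Scg2 2.78, Marcks -5.63, Ccl22 -2.99, Gbp2 -2.58 and Ppfia3 -2.28; the call of Acod1 was lost in 12 of 16 omissions, without a filter (adjusted p = 0.0697), in the fit of only the groups compared (0.0633) and with the replicate block (0.0758). Without GFP line 0 h replicate 2, the distant library for Acod1 at 0 h, its log2 difference at 5 h was -1.833 (adjusted p = 7.6e-08). Kcnq1ot1 overlaps Kcnq1 on the other strand and Gbp2 has close relatives, so their reads could belong in part to those genes, which was not tested. Scg2 was near the floor in the Nur77 line, with 5, 33 and 48 counts summed over its libraries at 0, 1 and 5 h. The size of the Scg2 differences is therefore uncertain.

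Each comparison of 2 groups was repeated on all other splits of its libraries and each interaction on 99 others, drawn at random within a time, with only those libraries fitted. For each of the 7 comparisons of 2 groups, 1 of 35 splits, the real one, gave as many called genes; the highest count of another split was 12, for LPS at 1 h in the Nur77 line. For the interaction 1 of 100 splits at 1 h (47 genes, 23 in the next) and 3 of 100 at 5 h gave as many, where the highest other split called 4411 genes against 2084. The larger splits at 5 h exchanged the line of the 0 h libraries, which adds the difference between the lines instead of subtracting it. Splits that mix the lines within a time put that difference into the spread, and the median count of the other splits was 0 for both interactions. These splits therefore do not show what would be called without an interaction, and no conclusion is drawn from them for the 2 interactions. In the 7 comparisons of 2 groups the other splits also put the real difference into the spread. Their low counts therefore do not measure false calls, and the rank of the real split shows only that the groups differ.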

How the results depend on the processing

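The mean over transcripts, the omission of NR_046233 and, without Nur77 line 1 h replicate 2, the list tests and the counts of comparisons that do not use that library were chosen after the data were seen. For 585 pairs of a named gene and a comparison, 8 kinds of alternative, without the omission of NR_046233, gave 9415 values. No call of these reversed, 9283 kept their side of the threshold, 31 gained a call and 101 lost it. DESeq2 size factors, the stricter filter and the mean over transcripts changed none of the 585.

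The replicate block, in which replicate numbers pair libraries across groups, gave 80 genes instead of 144 for the 1 h interaction and left the other counts within 1.5 times. The check for pairing was not met in any pair of groups. The highest mean correlation between libraries of equal number was 0.11, for the lines at 0 h, with values of 0.137, 0.17, -0.012 and 0.146; there 3 of 4 libraries correlated best with their own number, a hint from the data and not from the design. For the 1 h interaction DESeq2 called 500 genes, the fit without a filter 95 and the fit of only the groups compared 47. Leaving out 1 library gave from 74 (GFP line 0 h replicate 4) to 1589 (Nur77 line 1 h replicate 1). For the 5 h interaction the fit of only the groups compared called 2084, and leaving out 1 library gave from 718 (GFP line 5 h replicate 3) to 1672 (Nur77 line 1 h replicate 2). LPS at 1 h in the Nur77 line had 3490 genes in the fit of only the groups compared. The cause was not tested.

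Leaving out 1 library gave 4196 to 5480 genes for the lines at 0 h, 5563 to 6742 at 1 h and 5066 to 6324 at 5 h, 1722 to 2653 and 7249 to 8032 for LPS at 1 h and 5 h in the GFP line, and 4607 to 6191 and 7711 to 8452 in the Nur77 line. It gave 2698 to 3369 genes that differed at all 3 times, and 21.29 to 27.32% of induced genes lower at 1 h and 32.71 to 39.85% at 5 h. Of 243 list tests 92 were called, 44 with an estimated correlation, 170 with fry, 76 on ranks, 91 with the replicate block and 102 without Nur77 line 1 h replicate 2. Calls of named genes lost in at least 0.5 of the omissions of 1 library were Ccl2 (7 of 8) and Acod1 (4 of 8) for the lines at 0 h, Scg2 (12 of 16), Ifih1 (9 of 16) and Herpud1 (9 of 16) in the 1 h interaction, and Acod1 (12 of 16) and Fdft1 (11 of 16) in the 5 h interaction. Without GFP line 0 h replicate 2 the log2 difference of Acod1 at 5 h was -1.833 (adjusted p = 7.6e-08). Depth limits genes with few counts, and with 1 line per construct no alternative separates Nur77 from the line.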

Other observations

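The tests without Nur77 line 1 h replicate 2 were chosen after the results were seen, and the others in this part were planned. Calls of some lists were gained without Nur77 line 1 h replicate 2, which enters the shared estimate of spread: at 0 h immediate early genes (adjusted p = 0.0267) and effector genes (0.0254), lower in the Nur77 line, and at 5 h MAP kinase feedback inhibitors (0.0363), higher. None of these was called with an estimated correlation (adjusted p = 0.416, 0.224 and 0.0937). Alternative activation, eicosanoid, oxidative stress and neutrophil lists were called in none of the 9 comparisons, with lowest adjusted p of 0.365, 0.138, 0.0849 and 0.178.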
